A study of Mus musculus with 8 samples.

How the data were processed

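RNA of 4T1 cells, a mouse mammary carcinoma line, was sequenced in 8 libraries, 4 carrying a control shRNA and 4 an shRNA against Etv5. Per the labels' protocols, total RNA was extracted, libraries were made with the TruSeq RNA kit and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a to the mm10 genome. Groups and replicate numbers were taken from the sample titles. The file headers give all libraries of a group the same construct name, so each group appears to hold a single shRNA. No label says whether replicates were separate cultures, so every p-value measures the spread between these samples, which may be technical.

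The deposited table holds 24787 rows, named by gene symbol, and 1 column for each of the 8 libraries. The values are a signal: per the file headers, the columns derive from coverage tracks, and the deposited values behave as the mean coverage per base of each gene after scaling to library depth. This reading came from the values themselves. Multiplied by transcript length they summed to between 743 and 774 megabases per library, and low values of single-exon genes came in steps of 1 covered base, for 86.7% to 93.6% of them within a tolerance of 0.1. The program that averaged coverage per gene and its annotation are not given in the sources used here. Because whole reads could not be recovered, read depth is unknown and no counting interval is given. The steps put a value of 1 on a 1 kb transcript at between 6382 and 8418 covered bases in the 8 libraries. Of the rows, 7088 were at 0 in every library, and 26 carried symbols that a spreadsheet had turned into dates; none of the latter is named. The annotation used here for transcript lengths and coordinates was GENCODE mouse release 21, on the mm10 assembly, and 98.3% of rows matched a transcript length. The length of a gene was that of its longest annotated transcript.

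The test, the gene lists, the rule for naming genes and the settings not said to be added were chosen before the data were examined. A count model had been chosen, with a log-scale test as the stated fallback for normalised values. The fallback was used, since the table holds no counts. Values were transformed as log2(value + 1), so fold changes on this scale understate the change of genes with low values; folds given as such are ratios of group means of the deposited values. Genes at 0.5 or more in at least 4 libraries were tested, 11731 in all. This filter replaced the planned count filter and was set after the table's unit was known, before any list or named gene was tested. Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, no covariate and all 8 libraries. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Etv5 was also tested by an exact two-sided permutation test of its deposited values.

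The comparison also used 28 gene lists with 632 entries, of which 611 entries were found in the table. They cover factors that recruit or expand myeloid cells, chemokines, NF-kB targets, antigen presentation, tumour cell programmes, other cell types and signs of RNA quality. The 25 lists with at least 3 tested members were tested with camera from limma, on log2(value + 1), at a preset correlation of 0.01. Each was repeated with an estimated correlation and with fry.

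Genes were named by a fixed rule. It took Etv5 and its relatives Etv4 and Etv1. It took up to 8 called genes with the largest change in each direction, with a mean of at least 5 in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes. It took a fixed set of immune genes, where tested, whatever their result. From each list that passed or held at least 3 called members it took up to 4 genes in the main direction and up to 2 in the other, by adjusted p. The rule's minimum of 5 was stated for depth-scaled counts and was applied to the deposited values. It gave 74 genes; which of them are described singly was decided after their values were seen, and the others are given as counts. Genes outside the rule also appear, chosen for mention with their results known. They include Bcl3, Tnip1, Slc7a5, H2-T23, H2-Q4, Tapbp, Gstm1, the leukocyte transcripts among the flagged results, and the genes added under Other observations.

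The settings also tried were median-of-ratios scaling, equal sums, no filter, a stricter filter at a value of 1, a pseudocount of 0.1, the replicate number as a block, and leaving out each library. Added after the data were seen were quantile normalisation, array quality weights, and removal of each library's trend with transcript length or with length and GC content, by lowess with a span of 0.3. Also added was the length correction without the third Etv5 shRNA library. Further count-based tests had been intended and were not run.

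The test was tried on simulated data, 10 sets of 11731 genes with the real means and spread, in which 200 genes were changed. With all 8 libraries, including the real deviation of the third Etv5 shRNA library, 2.54% of genes changed by 0.5 on the log2 scale, 38.5% of those changed by 1 and 85.5% of those changed by 2 were recovered. Without the third Etv5 shRNA library the shares were 44.2%, 87.2% and 99.5%, and 5.12% of calls were false. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.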

Results

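RNA was measured in 8 libraries of 4T1 cells, 4 with a control shRNA and 4 with an shRNA against Etv5, which encodes an ETS-family transcription factor of the PEA3 group. The series concerns how ETV5 made by tumour cells bears on myeloid-derived suppressor cells, immune evasion and the response to checkpoint inhibitors. The comparison asks which transcripts of the tumour cell differ when Etv5 is targeted. Values are depth-scaled mean coverage per base of a gene, called coverage values. They summed to between 254792 and 390495 per library, and between 13920 and 15379 genes were above 0.

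Etv5 itself lies on chromosome 16, from 22381309 to 22439719 on the minus strand of mm10. Its coverage value was 14.1 ± 1.65 (SD, n = 4) with the control shRNA and 11.1 ± 2.52 (SD, n = 4) with the Etv5 shRNA. The controls held 15.2, 15.1, 11.7 and 14.4, and the Etv5 shRNA libraries 13.04, 11.2, 7.52 and 12.7, so the groups overlapped and Etv5 did not separate the libraries by label. The log2 fold change was -0.33 (95% interval -0.76 to 0.09), with an adjusted p of 0.819 by limma. An exact two-sided permutation test gave p = 0.0857 over 70 assignments, where the smallest possible was 0.0286. Without the third Etv5 shRNA library the log2 fold change was -0.17 and the adjusted p by limma 0.422. A lower Etv5 transcript level was thus not resolved from the spread between libraries. Of the 50-base stretches of its longest transcript, 26.8% also occur in Gm4798, a processed pseudogene, so part of the coverage of Etv5 is uncertain. Its relatives Etv4 (48.1 ± 3.13 and 38.8 ± 4.07, SD, n = 4 each) and Etv1 (8.87 ± 1.14 and 6.78 ± 2.29) did not pass the test either. For Etv4 the groups did not overlap, at 44.9 to 51.7 in controls and 34.8 to 43.7 with the Etv5 shRNA. The same held for 9.1% of all tested genes. For Etv1 the groups overlapped.

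Lcn2, Cxcl5, Cxcl1 and Csf3 fell the most in the Etv5 shRNA libraries on the log2(value + 1) scale, among named genes with a control mean of at least 5. Lcn2, which encodes an iron-siderophore binding protein, was 75.1 ± 10 (SD, n = 4) in the controls and 1.48 ± 0.605 (n = 4) with the Etv5 shRNA, 50.7-fold lower. The neutrophil chemokines Cxcl5 and Cxcl1 were 22.7-fold and 10.6-fold lower. Csf3, which encodes the granulocyte growth factor G-CSF, went from 133 ± 14.8 to 22.6 ± 1.65 (SD, n = 4 each), 5.91-fold. Complement C3, the cytokine Il1a, the RNase gene Zc3h12a and the chemokine Ccl20 were 6.46-fold, 5.96-fold, 6.77-fold and 7.88-fold lower. These are the 8 largest decreases by the fixed rule, and the limma log2 fold changes ran from -4.96 for Lcn2 (SE 0.201, adjusted p 1.4e-05) to -2.27 for Ccl20 (SE 0.239, adjusted p 0.00377).

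The third Etv5 shRNA library stood apart from the rest. Its coverage values summed to 390495, the highest of all, with the fewest genes above 0, at 13920. Ribosomal protein genes made up 15.7% of its summed values, against 5.92% to 8.84% in the other 7 libraries. The first principal component, with 81.9% of the variance, placed it at 93.4, and the next highest library, control shRNA replicate 3, at 12.8. Relative to the median library its median lay at 0.33 on the log2 scale in the 25% of genes with the shortest transcripts, and at -1.04 in the 25% with the longest. Results without this library are therefore given beside those over 8 libraries; this comparison was chosen after the data were seen.

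**Figure D1:**
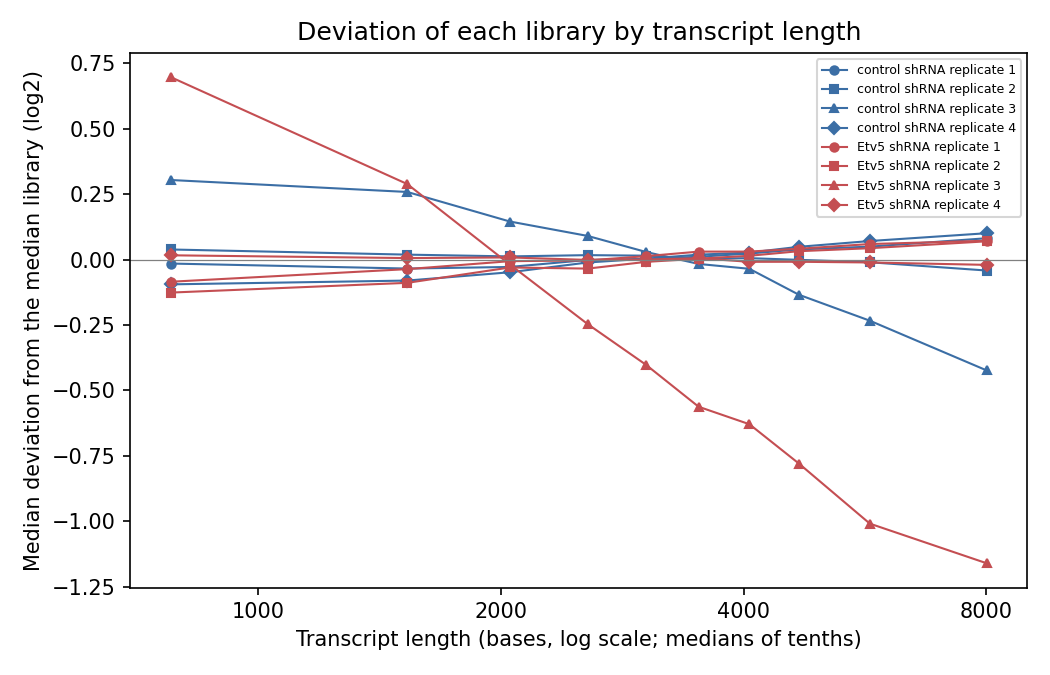
Median deviation of each library from the median library, on the log2(value + 1) scale, in 10 bins of the tested genes by transcript length in bases (log scale). Each line is 1 library, in blue for control shRNA and red for Etv5 shRNA. The third Etv5 shRNA library falls with length, and the third control library does so less steeply.

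Of 11731 genes tested, 57 were lower and 1 was higher with the Etv5 shRNA by limma, 38 of them by at least 1 on the log2(value + 1) scale. The higher gene was Ctgf, a matricellular protein gene and YAP target, at 33.7 ± 3.28 in controls and 59.2 ± 5.18 (SD, n = 4 each), adjusted p 0.0442 by limma. Its call was lost when any library other than the third Etv5 shRNA library was left out (adjusted p 0.0901 to 0.24), and with equal sums, a pseudocount of 0.1 or quantile normalisation, among other settings. In all 58 the libraries of one group did not overlap those of the other, as in 1067 of all tested genes (9.1%), where chance gives 2.86%. Without the third Etv5 shRNA library, 127 genes were higher and 241 lower, and all 58 were called again in the same direction. Among the Etv5 shRNA libraries then left, replicate 2 deviated with GC content, at a rank correlation of -0.557. GC content took up 24.7% of the variance of its deviation, against at most 6.14% in any other library. No setting removed the GC trend without the third Etv5 shRNA library. Leaving out control replicates 1 to 4 gave 31, 28, 32 and 30 lower genes, and leaving out Etv5 shRNA replicates 1, 2 and 4 gave 37, 33 and 32, with at most 1 higher. With median-of-ratios scaling 7 were higher and 49 lower, and the median log2 fold change of all genes was 0.02 in place of -0.11. Of the 74 genes named by rule, 1 was higher, 16 lower and 57 not called, the last with log2 fold changes from -0.98 to 0.76.

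**Figure D2:**
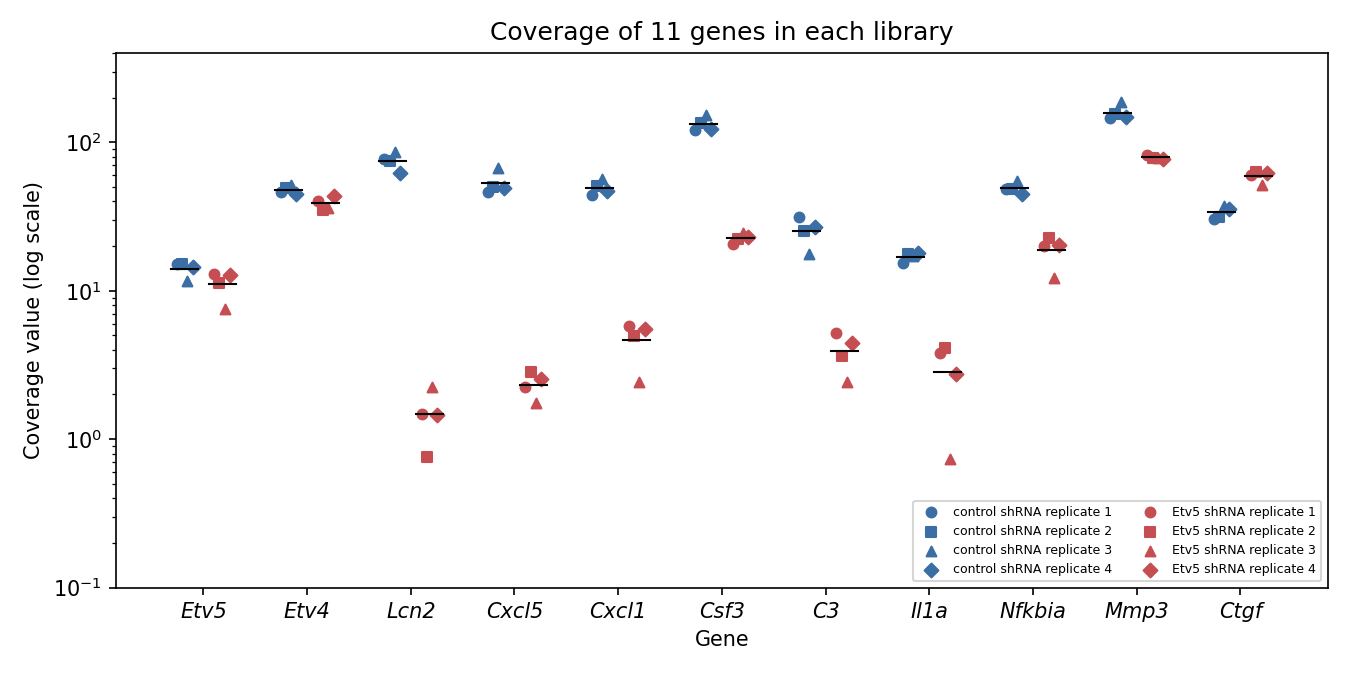
Coverage value (log axis) of 11 genes in each library, in blue for control shRNA and red for Etv5 shRNA; the symbol shows the replicate number and the black line the group mean. Etv5 overlaps between groups, whereas Lcn2 falls from a mean of 75.1 to 1.48 and Ctgf rises from 33.7 to 59.2.

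Genes for factors that recruit or expand myeloid cells were lower as a list. Of 13 tested members, 5 were lower (Cxcl5, Cxcl1, Csf3, Il1a and Ccl2), none higher and 8 not called; adjusted over the list alone, 6 were lower. Ccl2, the monocyte chemokine, was 3.74 ± 0.730 in controls and 0.265 ± 0.303 (SD, n = 4 each). Camera gave an adjusted p of 1.29e-12, and 0.0323 with an estimated correlation. With the third Etv5 shRNA library left out, 7 members were lower, among them Lif and Csf2 (adjusted p 0.00854 and 0.0306 by limma). Il1a lost its call by limma without any 1 control or Etv5 shRNA replicate 4 (adjusted p 0.0688 to 0.0901), with equal sums (0.0511) and with a pseudocount of 0.1 (0.0696). With the length trend removed the adjusted p of the list with an estimated correlation was 0.141. Csf1 was 34.0 ± 2.75 and 24.9 ± 8.53 and was not called. Another 14 members lay under the filter, including Cxcl2, Il6, S100a8 and S100a9, none above 1.09 in any library.

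The list of T cell chemokines had 5 tested members, of which Ccl20 was lower and 4 were not called; adjusted over the list alone, 3 were lower. Camera gave an adjusted p of 2.90e-05, and 0.0323 with an estimated correlation. Cxcl16 was 40.6 ± 1.41 and 23.01 ± 4.29 and Cx3cl1 20.8 ± 2.06 and 10.8 ± 2.95 (SD, n = 4 each). Neither was called in the main test over 8 libraries, and both were called lower by limma without the third Etv5 shRNA library, at adjusted p 0.00131 and 0.00955. Over 8 libraries Cx3cl1 was called lower by limma with median-of-ratios scaling (adjusted p 0.0473), quantile normalisation (0.0292) and the length trend removed (0.0189), and Cxcl16 with equal sums (0.0346). Without that library the list kept its camera call, while its adjusted p with an estimated correlation was 0.0535, and 0.0558 with the length trend removed over 8 libraries.

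NF-kB target genes were lower as a list as well. Of 21 tested members, 4 were lower (Lcn2, C3, Nfkbia and Ikbke), none higher and 17 not called; adjusted over the list alone, 10 were lower. Nfkbia, which encodes the inhibitor IkBα and is itself induced by NF-kB, was 49.3 ± 4.04 and 18.8 ± 4.51 (SD, n = 4 each). Ikbke, a kinase gene, was 14.4 ± 0.963 and 6.51 ± 0.536. Camera gave an adjusted p of 3.78e-12, and 0.0323 with an estimated correlation. Leaving out the third Etv5 shRNA library gave 8 lower members. Ikbke lost its call by limma without control replicate 1, 2 or 4 (adjusted p 0.051 to 0.0635), and Nfkbia without any library but Etv5 shRNA replicates 2 and 3 (0.0627 to 0.0917). Ikbke also lost it with median-of-ratios scaling (adjusted p 0.137 by limma), quantile normalisation (0.0664) and the length trend removed (0.221), and Nfkbia with equal sums (0.134). With an estimated correlation no list was called without control replicate 3 or 4 or without Etv5 shRNA replicate 1, 2 or 4. Among the members not called, Sod2 (11.2 and 13.5) and Nfkbib (7.87 and 8.67) had the higher mean with the Etv5 shRNA. All other members not called had negative log2 fold changes, from -0.15 for Rel to -0.99 for Bcl3 (adjusted p 0.0833 by limma). Tnip1 was at -0.62 (adjusted p 0.131 by limma). The median log2 fold change of the list was -0.42, against -0.11 for all genes.

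Matrix remodelling genes were lower by camera, at an adjusted p of 0.000191, but not with an estimated correlation (adjusted p = 0.567). Of 20 tested, 3 were lower: the collagenase gene Mmp13 (6.08 ± 0.486 and 1.05 ± 0.294), the protease inhibitor gene Serpine2 (48.0 ± 0.303 and 19.1 ± 1.52) and the stromelysin gene Mmp3 (159 ± 18.7 and 79.2 ± 2.16; SD, n = 4 each). None was higher, and 8 were lower when adjusted over the list alone. Leaving out the third Etv5 shRNA library gave 6 lower and 1, the metalloprotease gene Adamts1, was higher (2.94 ± 0.620 with n = 4 and 6.90 ± 0.430 with n = 3). The list of PEA3 factors and ERK feedback genes was lower by camera (adjusted p 0.00796), and not with an estimated correlation (adjusted p = 0.747). Of its 21 tested members only Ier3, an early response gene, was called, at 91.9 ± 10.7 and 45.6 ± 7.04 (SD, n = 4 each), and likewise over the list alone. Mmp3 lost its call by limma without control replicate 1, 2 or 4 or Etv5 shRNA replicate 1, 2 or 4 (adjusted p 0.0556 to 0.082), and Ier3 without any library but Etv5 shRNA replicate 3 (0.0692 to 0.151). Median-of-ratios scaling ended both calls (adjusted p 0.182 for Mmp3 and 0.0724 for Ier3 by limma), and Ier3 was not called with equal sums (0.152) or with the length trend removed (0.101) either. This list, without the third Etv5 shRNA library, was not called, at an adjusted p of 0.405 by camera, with Ier3 and Lif lower and the feedback inhibitor Spry1 higher.

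Camera placed 6 lists higher than other genes, in none of which a member was called higher over 8 libraries. None held with an estimated correlation, and the third Etv5 shRNA library moved with several of them. For cholesterol synthesis the adjusted p was 6.32e-06, and 0.336 with an estimated correlation; 1 of 19 members was higher over the list alone. With the third Etv5 shRNA library left out, 6 of the 19 were higher, among them Msmo1, which encodes an enzyme of the pathway (20.4 ± 2.13 with n = 4 and 35.5 ± 2.20 with n = 3). For the list of ATF4 targets and the unfolded protein response the adjusted p was 7.54e-06, and 0.313 with an estimated correlation. Without that library 4 of 24 were higher, among them Atf3 and Mthfd2. The amino acid transporter gene Slc7a5, outside the rule, was also higher (102 ± 7.44 with n = 4 and 153 ± 3.74 with n = 3).

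Ribosomal protein genes, 49 tested and none called, had an adjusted p of 1.21e-05 toward higher values by camera, and 0.747 with an estimated correlation. The direction turned without the third Etv5 shRNA library, to lower at an adjusted p of 4.38e-05 by camera (0.656 with an estimated correlation), and with quantile normalisation, at 0.854. Rpsa was 3503 in that library and between 772 and 799 in the other 3 of its group; genes of this family have many near-identical pseudogenes, so their values are uncertain. Oxidative phosphorylation, with 34 tested and none called, had an adjusted p of 1.36e-05 (0.747 with an estimated correlation), and 0.704 by camera without that library, toward lower values. G2/M genes had an adjusted p of 0.0487 (0.747 with an estimated correlation) with none of 22 called, although their median log2 fold change was -0.01, since that of all genes was -0.11; the call was lost with equal sums and when some single libraries were left out. Without the third Etv5 shRNA library the G2/M adjusted p was 0.000279 (0.142 with an estimated correlation). Epithelial genes had an adjusted p of 0.0044 (0.313 with an estimated correlation), and 0.103 without the third Etv5 shRNA library. Their 1 called gene of 23, the ETS factor gene Ehf, was lower, at 2.37 ± 0.336 and 0.107 ± 0.0528 (SD, n = 4 each).

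**Figure D3:**
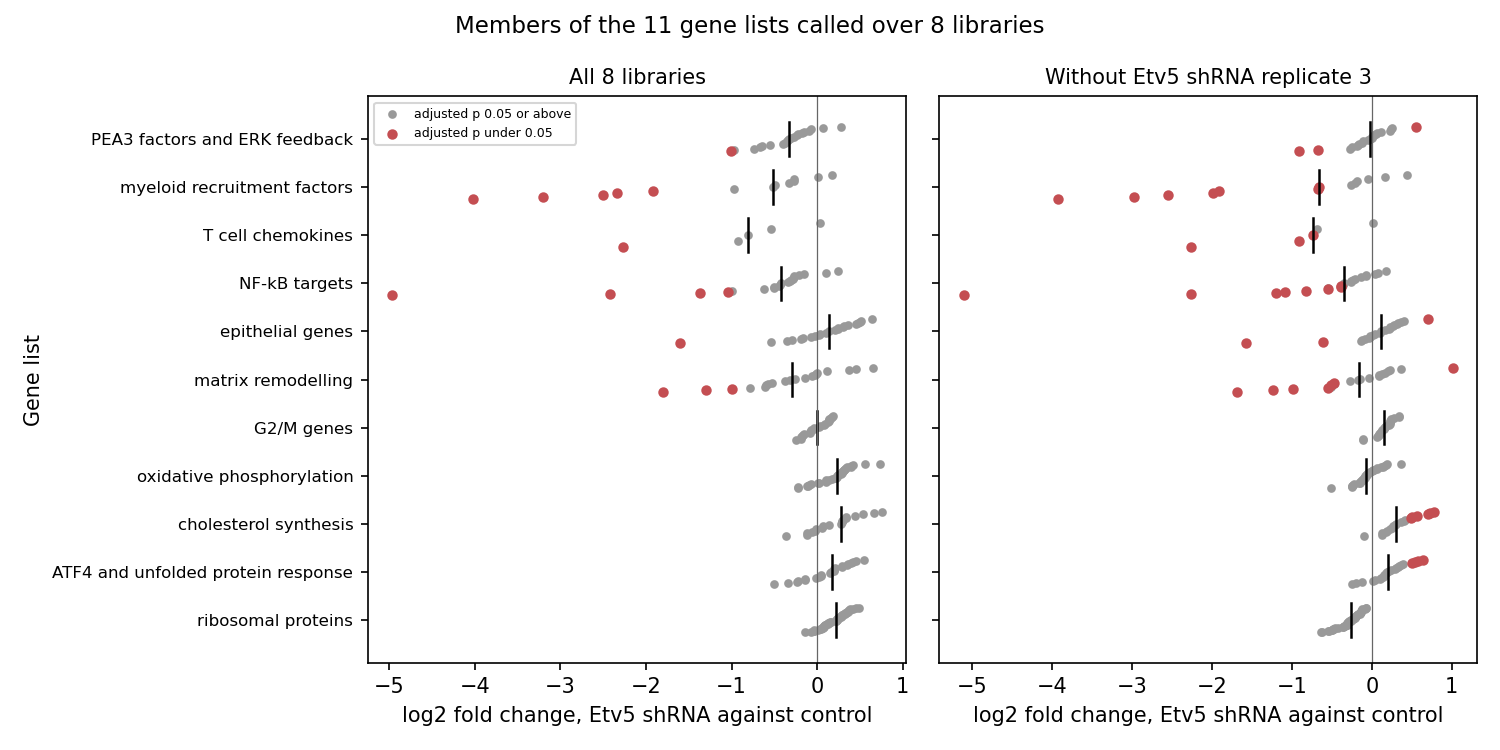
Log2 fold change, Etv5 shRNA against control shRNA, of each tested member of the 11 lists called by camera over 8 libraries, with all libraries (left) and without the third Etv5 shRNA library (right). Red points had an adjusted p under 0.05 by limma, grey points did not, and black bars are list medians. Ribosomal proteins have a median of 0.22 on the left and -0.26 on the right, and their direction by camera also turned with quantile normalisation.

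Antigen presentation by MHC class I did not pass as a list over 8 libraries, at an adjusted p of 0.378 by camera, with none of 19 members called and 2 lower over the list alone. B2m was 500 ± 104 and 501 ± 35.6, and H2-K1 10.3 ± 3.03 and 9.07 ± 1.56 (SD, n = 4 each). The list was called lower without the third Etv5 shRNA library by camera (adjusted p 0.00481, and 0.439 with an estimated correlation). H2-T23, H2-Q4 and Tapbp, all outside the rule, were then lower. The H2 genes, H2-K1 included, are related in sequence. Sequence shared among them was not searched for, so the coverage of each is uncertain. Checkpoint ligands had an adjusted p of 0.0974 by camera, with none of 12 called. Cd274, which encodes PD-L1, lay under the filter, with values from 0.0883 to 0.796.

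The 12 other tested lists were not called by camera over 8 libraries. In interferon-stimulated genes (20 tested), mesenchymal genes (10), DNA replication (22), glycolysis and hypoxia (21), fatty acid and lipid synthesis (21), p53 targets (12), Wnt targets (9) and histones (6) no member was called. The list of YAP and TGF-beta targets had 1 of 17 higher, Ctgf, and the list of immediate early genes 1 of 23 lower, Ier3. The NRF2 list had 1 of 19 lower, Gstm1 (outside the rule, and uncertain, having near-identical copies). With the length trend removed no member of the NRF2 list was called. Fatty acid and lipid synthesis was called higher by camera without the third Etv5 shRNA library, at an adjusted p of 0.00116 (0.362 with an estimated correlation). Camera placed YAP and TGF-beta targets, glycolysis and hypoxia, fatty acid synthesis, NRF2, Wnt and histones toward higher although their medians lay below 0, and for DNA replication and histones mean and median differed in sign. Of 24 leukocyte markers 3 passed the filter and none was called. Endothelial and fibroblast markers had too few members above the filter for a test, and the 13 mitochondrial transcripts have no row.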

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

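All tests in this part were chosen after the results were seen, except the search for shared sequence of Etv5. Median-of-ratios scaling was a setting chosen beforehand, but its use here to weigh the called members was not. Each group of 4 libraries was screened for 1 library far from the other 3, by Dixon's ratio of the gap to the range at the 95% critical value, over the 74 genes named by rule and 9 library measures. Of 166 groups, 32 passed, where chance gives 8.3, and in 26 the library was the third Etv5 shRNA library.

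Among library measures, the third Etv5 shRNA library was the highest of its group in the sum of values (390495, ratio 0.868), the share of the top 10 genes (12.6%, ratio 0.908) and the ribosomal protein share (15.7%, ratio 0.914). It was also the highest on the first principal component (93.4, ratio 0.907) and in the SD of its deviation from the median library (0.902, ratio 0.909). It was the lowest in genes above 0 (13920, ratio 0.912). The third control library was the lowest of its group in genes above 0 (15126, ratio 0.850).

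In single genes, the third Etv5 shRNA library was the highest of its group for Rpsa (3503, ratio 0.990), Rpl14 (2359, ratio 0.968), Cdk1 (80.4, ratio 0.956), Rps2 (425, ratio 0.936), Uqcrq (192, ratio 0.919) and Cycs (29.6, ratio 0.917). The same held for Fdps (81.7, ratio 0.911), Sdhb (174, ratio 0.893), Mmp14 (94.0, ratio 0.883) and Mif (927, ratio 0.834). It was the lowest for Csf1 (12.1, ratio 0.956), Kif20a (13.1, ratio 0.948), Spry1 (12, ratio 0.912), Egr1 (2.53, ratio 0.900) and Xbp1 (9.02, ratio 0.900). The same held for Lif (3.25, ratio 0.886), H2-K1 (6.75, ratio 0.854), Ocln (2.02, ratio 0.848), Adamts1 (1.91, ratio 0.842) and Mmp13 (0.614, ratio 0.831). The third control library was the highest for Ier3 (108, ratio 0.927), Cdc20 (77.1, ratio 0.896), Rps2 (171, ratio 0.891) and Ccl2 (4.82, ratio 0.862), and the lowest for Csf1 (29.9, ratio 0.848).

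The third Etv5 shRNA library deviated from the median library with an SD of 0.902 on the log2 scale. Removing its trend with transcript length left an SD of 0.711, against at most 0.24 in the other libraries. The length used was that of the longest annotated transcript, which may not be the one expressed. A bias with length could therefore remain after the removal, and the test does not decide whether length was the whole cause. A stronger response to the shRNA would place it further from the controls. Of the 127 genes called higher without it, it lay above the mean of its group's other 3 in 11%, against 31.1% of all genes. Of the 241 called lower it lay below that mean in 62.7%, against 68.9% of all genes. Set against 1 library kept out of choosing the genes, it was above in 0% to 8.33% of the 11, 15 and 48 genes called higher. It was below in 67.1% to 72.9% of those called lower, against 67.9% to 69.3% of all genes. Etv5 was the lowest of its group in it (7.52). So were Cxcl5, Cxcl1, C3, Il1a and Zc3h12a of the 8 largest decreases, whereas Lcn2 and Csf3 were the highest and Ccl20 was neither. The shares were taken with the length trend left in and without matching genes by length. They therefore do not decide whether this library responded more strongly. Across genes, which are not independent replicates, its deviation correlated by 0.647 with that of the third control library after the length trend was removed from both (-0.189 to 0.385 with the other 6), and by 0.571 on average where the 2 deviations were taken from references that share no library (-0.359 to 0.228 with the others), so a shared library difference may account for part of it. Such a difference may include a bias with length that the removal left in both libraries. RNA quality and differences in preparation between single libraries are not recorded and remain open.

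Etv5 transcript was 79.0% of control with the Etv5 shRNA while cytokine genes fell many-fold. If transduced cells held no Etv5 transcript and all its coverage were its own, untransduced cells would leave every gene at the share they bring. That share would be at least 59% from the interval of Etv5, or 74.9% without the third Etv5 shRNA library. Both bounds come from the log2(value + 1) scale. By group means of the deposited values, the 9 called genes of the myeloid and NF-kB lists kept at most 45.1%. On the log2(value + 1) scale their changes over 8 libraries were -1.04 or lower, against -0.76 at the lower end of the Etv5 interval. These genes were chosen for being lower. A smaller share of untransduced cells, with some Etv5 transcript left in the others, is not excluded. The trend with transcript length did not hide a large drop, since its removal gave a log2 fold change of -0.188 with an interval of -0.40 to 0.03. Coverage from another gene may be counted as Etv5, since 26.8% of its 50-base stretches occur in the pseudogene Gm4798, which has no row in the table, and none in Etv1 or Etv4. A loss of protein without loss of transcript, and an effect of the shRNA on other transcripts, were not tested and stay open.

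Lower NF-kB and myeloid recruitment genes were weighed over their 9 called members. Being chosen for their falls in these same data, these members say little about those with smaller changes. With the length trend removed 8 were still called lower, and with median-of-ratios or quantile scaling 8 under each; with the length trend removed the adjusted p with an estimated correlation was 0.032 for the NF-kB list and 0.141 for the myeloid list. The exception was Ikbke in every case, with a log2 fold change of -1.04 (SE 0.124), and -0.85 (SE 0.267), -0.88 (SE 0.185) and -0.94 (SE 0.175) under these settings, where the larger error ended the call. Leukocytes in the control cultures would bring their abundant transcripts, but Ptprc, Tyrobp, Laptm5, Fcer1g and Lyz2 averaged at most 0.138 in the controls; Cd68, Cd14 and Cd74, the 3 markers above the filter, averaged 3.8, 4.93 and 8.99 there and 3.13, 3.49 and 6.99 without the third Etv5 shRNA library, none called, with an adjusted p of 0.0268 for the list toward lower by fry in limma. These tests leave an effect of the shRNA as a hypothesis. They do not separate the loss of Etv5 from other effects of the shRNA. Nor do they separate it from other differences between the cells of the groups.

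Both counts of calls were set against every other split of the libraries. The splits cannot go below 1 in 35, and they cannot exclude a chance difference between cultures if the replicates are technical. The count without the third Etv5 shRNA library also rests on a choice made after the data were seen. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called 58 genes, and the highest other called 0. Without the third Etv5 shRNA library, again only 1 of 35 splits, the real one, called as many as the 127 higher and 241 lower genes, and the highest other called 0.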

How the results depend on the processing

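The alternatives with quantile scaling, array weights, and length or GC corrections were chosen after the data were seen; where a count moved, the cause was not tested unless stated. The planned DESeq2 and limma-voom fits were not run because they need counts. Etv5 kept its direction in every setting, with log2 fold changes from -0.42 to -0.17 when 1 library was left out. It passed the threshold only with array quality weights (-0.19, adjusted p 0.0392; other adjusted p from 0.206 to 1.00), where the weights did not converge and ran from 0.0265 to 10.7.

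Genes higher and lower, 1 and 57 over 8 libraries, became 7 and 49 with median-of-ratios scaling, 0 and 42 with equal sums, 3 and 70 with no filter, and 0 and 37 with a pseudocount of 0.1. They became 7 and 64 with quantile normalisation, 1513 and 1670 with array weights, 22 and 92 with the length trend removed, 41 and 125 with the GC trend removed too, and 426 and 516 with the length trend removed without the third Etv5 shRNA library. With 1 library left out, higher genes ranged from 0 to 127 and lower genes from 28 to 241, both highest without Etv5 shRNA replicate 3. Without control replicates 1 to 4, lower genes were 31, 28, 32 and 30, and without Etv5 shRNA replicates 1, 2 and 4 they were 37, 33 and 32. Genes changed by at least 1 on the log2(value + 1) scale ranged from 25 to 49.

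Lists called by camera, 11 in the main test, ranged from 10 to 12 when 1 library was left out, were 8 with quantile normalisation, and were 3 with an estimated correlation and 4 by fry. Fry called 11 without Etv5 shRNA replicate 3, and 13 with the length trend removed too. With an estimated correlation no list was called with equal sums, with the replicate block, or without control replicate 3 or 4 or Etv5 shRNA replicate 1, 2 or 4, and 1 with the length trend removed, with length and GC removed, or with array weights. The direction of the list ribosomal proteins by camera turned to lower without Etv5 shRNA replicate 3 (adjusted p 4.38e-05) and with quantile normalisation (0.854). It also turned with array weights (3.1e-05) and with the length trend removed without that library (0.000652). Its adjusted p by camera ranged from 1.51e-10 to 0.00214 when 1 library was left out. Over 8 libraries with the length trend removed, the list stayed toward higher values but was not called (adjusted p 0.0868 by camera). Oxidative phosphorylation turned too without Etv5 shRNA replicate 3 (0.704, with 1.6e-08 the lowest when another library was left out). So did the epithelial list by fry (0.992), and Dhcr7 with array weights (log2 fold change 0.23). Without Etv5 shRNA replicate 3, 10 of the 74 named genes, among them Mif, Ocln, Kif20a, Rpsa and Dhcr7, differed in sign from the value over 8 libraries, none called in either.

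Same-numbered libraries of the 2 groups deviated together by 0.549, 0.0924, 0.794 and 0.51, not all over 0.1. Of 8 libraries, 3 correlated best with their own number. Deviations were taken from group means, which the third library of each group pulls away from the others. Positive correlations can therefore arise without pairing. The numbers were not taken to pair the samples, although a shared origin of some pairs is not excluded. With the replicate block 1 gene was higher and 50 lower, 39 of the 58 genes were shared, Ctgf and Ier3 were not called, and the adjusted p with an estimated correlation was 0.388 for the NF-kB, myeloid and T cell lists. Of the named genes, Ctgf, Il1a, Ier3, Nfkbia, Ikbke and Mmp3 lost their call under at least 1 setting, and the other called ones kept it wherever tested. Read depth in whole reads is unknown, so it is not said what depth limits. By the steps of 1 covered base, a value of 1 on a 1 kb transcript stood for 7576 covered bases in the third Etv5 shRNA library. The range over the 8 libraries was 6382 to 8418.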

Other observations

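The 2 list tests here were fixed before their results were seen, but both were prompted by genes noticed in these data, so their outcome is a hypothesis. The genes in the next paragraph were chosen after their values were seen.

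Nfkbiz, which encodes the atypical IkB protein that activates secondary NF-kB targets, was 19.6 ± 1.59 in controls and 4.21 ± 1.66 with the Etv5 shRNA (SD, n = 4 each), with an adjusted p of 0.0113 by limma. Cebpd, a transcription factor gene of the acute phase, was 5.75 ± 1.23 and 1.71 ± 0.705 (adjusted p 0.0338 by limma), and was not called with the length trend removed (0.13). Ptges, the prostaglandin E synthase gene, was 8.46 ± 1.2 and 2.84 ± 0.467 (adjusted p 0.00675 by limma). Slpi, a secreted protease inhibitor gene, was 45.2 ± 8.12 and 13.2 ± 7.92 and was not called over 8 libraries (adjusted p 0.0657 by limma). It was called without the third Etv5 shRNA library, at 9.31 ± 2.23 (n = 3), and with the length trend removed. Not called over 8 libraries and called higher by limma without the third Etv5 shRNA library were the adhesion gene Cdh1 (38.5 ± 3.49 with n = 4 and 63.3 ± 2.87 with n = 3) and Thbs1 (42.1 ± 7.77 and 73.9 ± 1.91).

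Ribosome biogenesis may be higher with the Etv5 shRNA. Utp4, Rrp12, Mphosph10 and Abce1 were noticed among the genes higher without the third Etv5 shRNA library, and 34 other genes of nucleolar ribosome assembly were then listed and tested. Camera placed them higher without that library at an adjusted p of 1.46e-11, and 0.0117 with an estimated correlation, with 8 members called higher, none lower and 30 of 34 above 0. With the length trend also removed the adjusted p by camera was 4.44e-11, and 0.0246 with an estimated correlation, with 11 called higher. Over 8 libraries no member was called, while camera gave 5.16e-14 and 31 of 34 lay above 0. Nolc1 was 36.3 ± 1.42 (SD, n = 4) and 50.4 ± 1.73 (SD, n = 3).

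Complement genes C3, C1s1 and C1ra and the acute phase genes Lcn2 and Serpina3h were among the genes called lower. Of the 20 other complement and acute phase genes then listed, only 2 passed the filter, fewer than the 3 required for a list test, so the camera value computed on those 2 is not read as a result for the group.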
